A study of Mus musculus with 6 samples.

How the data were processed

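The series holds 6 polyA RNA-seq libraries of AML12 cells, an immortalised mouse hepatocyte line, transfected with a construct that carries either the open reading frame of Zac1 or that of EGFP, a fluorescent protein used as the control. RNA was taken after 24 h. Each group has 3 libraries, which carry the numbers 1, 2 and 3 (EGFP) and 4, 5 and 6 (Zac1) in the labels. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

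The authors deposited 1 table of read counts per gene, with 1 column per library and no pooling of replicates. Per the submitters' processing notes, FastQC, STAR, HTSeq and DESeq2 were used, with no versions or settings. The genome build and annotation are not given in the sources used here. Per the labels' protocols, RNA was treated with DNase and the libraries were made with a directional kit; whether the counting used strand is not stated, so reads of overlapping or antisense genes may not be told apart. The table is called normalized where it was deposited, but its values behave as unscaled counts. All of them are whole numbers, the library totals run from 14801240 to 18302538, and median-of-ratios factors run from 0.928 to 1.162. In each library 0 of the whole numbers from 1 to 40 are absent, where scaling by 1.15 and rounding would leave 5 absent. The design fixed before the data were examined had assumed values already divided by size factors, with limma on log2(value + 1). Since the deposited values are counts, a count test replaced it as the main test, and the fit first written is given among the alternatives.

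Genes carry Ensembl mouse IDs. Symbols were taken from the GENCODE M21 name table, which matched 49326 of the 49585 IDs; 259 did not match. Coordinates are those of GENCODE M21 (GRCm38), looked up by gene ID. EGFP was not analysed here.

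Genes with a mean count of at least 10 over the 6 libraries were tested (12130 genes; 27821 were at 0 in every library). Counts were scaled by TMM factors and tested for Zac1 minus EGFP, two-sided, with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, prior count 0.125 for log2 fold changes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled library size and are given as mean ± SD with n = 3. Where EGFP libraries held 1 to 3 reads in all, the ratio of summed counts is given with an exact 95% interval (Clopper-Pearson); where they held 0, the ratio is a lower bound against 3 counts over the group. These intervals and bounds cover counting error only.

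Before the data were examined, 27 gene lists were fixed. The 23 lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 1, Plagl1 left out), with adjustment over the 23 lists; camera with an estimated correlation and the rotation test fry were alternatives. The text names Plagl1; the 10 largest rises and the 10 largest falls among genes past the test with no overlap between the groups, a mean count of at least 50 and no predicted-gene, RIKEN or pseudogene symbol; and up to 4 members past the test, by p, of each list that camera called and of 6 lists named in any case (imprinted, extracellular matrix, TGF-beta, fatty acid synthesis, fatty acid oxidation, hepatocyte), or the 2 with the smallest p as values where none passed. Some genes that this rule takes are not reported here. Other genes are said to have been chosen after their values were seen.

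Replicates were compared before they were averaged. Pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.29 to 8.83. The fit was tested on simulated counts for the 12130 genes of the Zac1 and EGFP comparison, with 200 genes changed: it recovered 80.6% of those changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold, and 11 false calls made up 5.9% of its calls. A simulated list shifted 1.15-fold was called, and 0 of 20 unmoved lists were. Genes were drawn independently of each other there, so false list calls from correlated genes were not examined by this simulation.

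Alternatives fixed in advance were other prior counts, filters and scalings, no trend or robust variance, library quality weights (run as voom weights), DESeq2 1.42.0, both other list tests and leaving out each library in turn. TMM scaling and the edgeR test, also fixed in advance as alternatives, became the main settings. Alternatives chosen after seeing the data were median-of-ratios scaling in edgeR, limma on log2(CPM + 1), leaving out EGFP 1 and Zac1 4 together, and offsets for the GC content of the longest transcript of each gene (12116 genes with a value). The GC offsets were computed in 2 versions, from a loess curve per library with a span of 0.5. The least-squares curve was run first. The robust curve was added after its result had been seen, on the reasoning that a least-squares curve would take up part of the large rises of GC-rich, low genes. Both versions are reported.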

Results

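The transcriptomes of AML12 mouse hepatocytes were measured 24 h after transfection with a Zac1 or an EGFP construct, with 3 libraries per group. Zac1 is a zinc-finger transcription factor encoded by the imprinted gene Plagl1. The series title names Zac1, a network of imprinted genes and juvenile fatty liver disease. The comparison of Zac1 with EGFP asks which transcripts differ once Zac1 is over-expressed in a hepatocyte line. Total counts were 15145092, 14885966 and 14801240 in EGFP replicates 1, 2 and 3. They were 16104498, 17003713 and 18302538 in Zac1 replicates 4, 5 and 6. The first principal component, with 58.8% of the variance, separated the groups. The second, with 15.5%, set EGFP replicate 1 (18.7) and Zac1 replicate 4 (11.6) apart from the other 4 libraries (-10.6 to -3.5).

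Plagl1 (ENSMUSG00000019817; GRCm38 chromosome 10, 13060504 to 13131694, plus strand) was read 39, 79 and 67 times in the EGFP libraries and 106033, 135108 and 148382 times in the Zac1 libraries. Its level was 4.14 ± 1.39 CPM in EGFP and 7538 ± 811 CPM in Zac1 (SD, n = 3), a log2 fold change of 10.83 (SE 0.15, adjusted p = 1.54e-15). In the Zac1 libraries it took 0.658%, 0.795% and 0.811% of all reads. The counts do not tell transcripts of the construct from those of the cells' own gene.

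Of 12130 genes tested, 459 differed between the groups; 378 were higher and 81 lower in Zac1. At least 2-fold changes were found for 186 of them, 175 higher and 11 lower, and the other 273 changed by less (203 higher, 70 lower). Of the 175 genes that rose at least 2-fold, 125 (71.4%) had a mean below 1 CPM in EGFP. That share is not tested, since the count minimum over all 6 libraries admits a gene near 0 in EGFP only if its Zac1 counts are high. With every library thinned to the same depth, 16608 ± 84.3 genes had a read in EGFP and 17401 ± 261 in Zac1 (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). The groups did not overlap for any of the 459 genes; across all tested genes this held for 20.6%, where chance gives 10%. The number of changed genes rested on single libraries. It was 963 without Zac1 replicate 4, 236 without EGFP replicate 3, 206 without Zac1 replicate 5 and 221 without Zac1 replicate 6. The number of higher genes was then 584, 214, 187 and 196, and that of lower genes 379, 22, 19 and 25; lower genes were 125 without EGFP replicate 1. The count of at least 2-fold changes was 122 without Zac1 replicate 5 and 122 without Zac1 replicate 6. Without EGFP 1 and Zac1 4, the libraries apart on the second component, 1461 genes changed, an alternative chosen after seeing the data. That edgeR fit and the one with no filter on low counts shared the variance almost wholly over genes (prior degrees of freedom of 1560 and infinity, against 10 in the main comparison), so their gene p-values are much smaller and are no firmer evidence. Fold changes also followed GC content across genes (Spearman's rho 0.4; genes are not independent replicates). Higher genes had a median transcript GC of 55.8% and lower genes one of 45.1%, against 49.4% for all. With offsets that remove a least-squares GC trend, 332 genes were higher and 621 lower. The share of higher calls was then 34.8%, against 82.4% without offsets. Those offsets also moved the median log2 fold change of all tested genes from -0.002 to -0.043. With a robust GC curve, adopted after the least-squares result was seen, 365 were higher and 111 lower (76.7%), and the median was -0.002. On unscaled counts, where the deeper Zac1 libraries are not corrected for, 3184 were higher and 23 lower (99.3%).

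**Figure D1:**
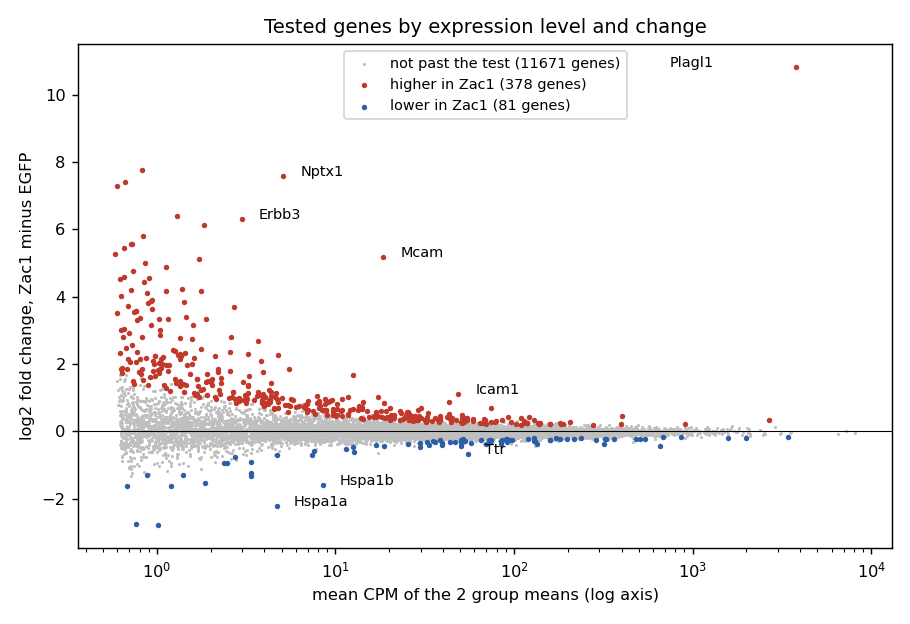
Log2 fold change (Zac1 minus EGFP) of the 12130 tested genes against the mean of both groups' CPM on a log axis; red points are the 378 genes higher and blue points the 81 genes lower in Zac1. Plagl1 stands at 10.83, and most other large rises lie at low CPM.

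The 10 largest rises after Plagl1 are given for genes with a mean count of at least 50; some genes below it had larger fitted changes. Nptx1, a secreted neuronal pentraxin, had 2 reads in all EGFP libraries and 523 in all Zac1 libraries, a ratio of 227 (95% interval 62.6 to 1880). The receptor tyrosine kinase gene Erbb3 had 3 and 305, a ratio of 88.3 (29.9 to 431). Mcam, a cell adhesion molecule, rose from 0.983 ± 0.454 to 35.9 ± 1.59 CPM (log2 fold change 5.18, SE 0.17, adjusted p = 2.52e-10). The Notch ligand gene Dll1 rose 6.45-fold, from 0.987 ± 0.478 to 6.38 ± 0.45 CPM, and Tcf7l1, a transcription factor of the Wnt pathway, rose 4.87-fold. Flt1, a VEGF receptor, rose 4.86-fold, Cacna1g, a T-type calcium channel subunit, 4.24-fold, and Ntn1, a secreted guidance cue, 3.6-fold. Cyp26b1, which degrades retinoic acid, rose 3.36-fold and the actin-organising gene Rflnb 3.17-fold. Adjusted p for these 10 genes was at most 0.000346, that of Cyp26b1, and each stayed past the threshold with any 1 library left out.

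The 10 largest falls by the same rule were smaller. The heat shock genes Hspa1a and Hspa1b, which encode inducible HSP70, fell from 7.7 ± 1.8 to 1.65 ± 0.0814 CPM (log2 fold change -2.22, SE 0.21) and from 12.8 ± 1.77 to 4.17 ± 0.619 CPM (-1.61, SE 0.15), both with adjusted p = 3.69e-05; they are near-identical copies, so how reads divide between them is uncertain. Log2 fold changes were -1.33 for Tmem236 and -1.23 for Mrc2, a collagen-binding endocytic receptor. Among liver-type genes, Ttr, the carrier of thyroxine and retinol-binding protein, fell by 0.67 on the log2 scale, from 67.4 ± 2.71 to 42.5 ± 4.47 CPM (SE 0.08, adjusted p = 0.000211), and Klb, a co-receptor for FGF hormones, fell by 0.61. The organic anion transporter gene Slco1a6 fell by 0.9, the amino acid transporter gene Slc3a1 by 0.7, haptoglobin (Hp) by 0.69 and the glycogen phosphorylase gene Pygm by 0.59. Those last 4 calls were lost when single libraries were left out. Slco1a6 was lost without EGFP 3 or Zac1 5 (adjusted p up to 0.107) and Slc3a1 without Zac1 5 or Zac1 6 (up to 0.0987). Hp was lost without EGFP 2, EGFP 3, Zac1 5 or Zac1 6 (up to 0.162), and Pygm without EGFP 2, EGFP 3 or Zac1 5 (up to 0.18). Hp and Pygm also did not pass on unscaled counts (0.0546 and 0.0693).

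**Figure D2:**
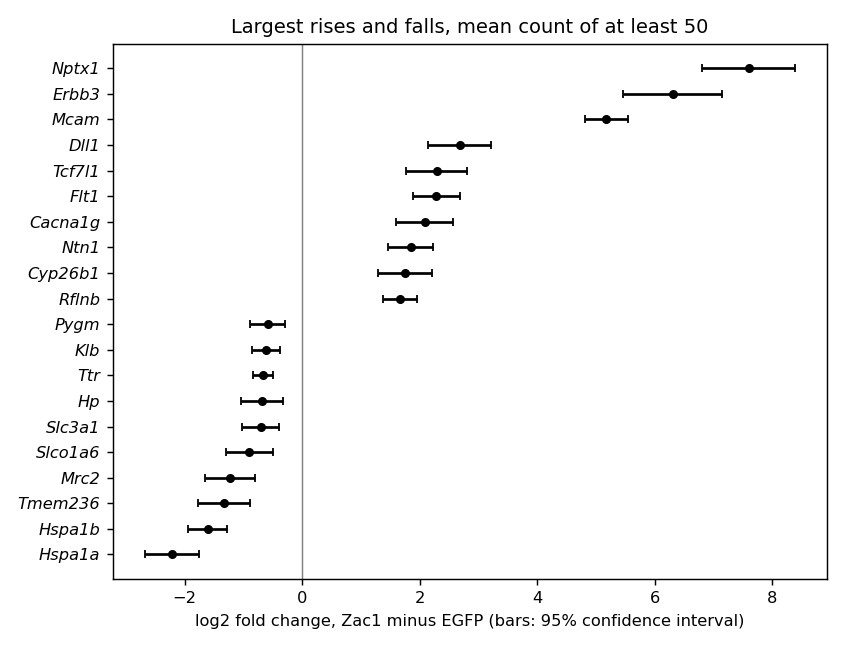
Log2 fold change (Zac1 minus EGFP, n = 3 per group) of the 10 largest rises and 10 largest falls among genes with a mean count of at least 50; points are fitted values and bars their 95% confidence intervals. Fitted values run from 7.6 for Nptx1 to -2.22 for Hspa1a; those of Nptx1 and Erbb3 rest on 2 and 3 EGFP reads and depend on the prior count.

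No gene on the fixed list of imprinted genes, which does not hold Plagl1, passed the edgeR test over all genes as higher. Imprinted genes outside that list were not looked up. Of 50 listed, 20 were tested, 30 were below the count minimum and 13 of those had 0 reads in every library. Of the 20, 0 were higher and 2 lower, Zrsr1 (log2 fold change -0.42, SE 0.1, adjusted p = 0.0274) and Airn (-0.43, SE 0.11, adjusted p = 0.0455); adjusted over the list alone, 1 was higher, Phlda2, and 2 were lower. At an unadjusted p under 0.05, 1 was higher, and DESeq2 called 0 as higher and voom with quality weights 1. Zrsr1 lies inside Commd1 and Airn is antisense to Igf2r, so reads of those partners may be among them. Their calls were lost without EGFP 2, Zac1 5 or Zac1 6, and for Airn also without EGFP 3 (adjusted p up to 0.117 for Zrsr1 and 0.224 for Airn). Airn was also lost with upper-quartile scaling, with scaling to the total with or without Plagl1, with a mean count of at least 50 and with limma on log2(CPM + 1) (adjusted p from 0.0505 to 0.072), and both were lost on unscaled counts (0.127 for Airn and 0.156 for Zrsr1). The list did not pass camera (adjusted p = 0.0853; 0.313 with an estimated correlation). Of growth-related members, chosen after their values were known, Cdkn1c and Grb10 each had 6 reads in all EGFP libraries and 20 in all Zac1 libraries. H19 had 2 and 6, and Igf2 had 0 and 3. Phlda2 had a log2 fold change of 1.12 (edgeR adjusted p = 0.0827 over all genes). Among the 20 tested members, 6 fold changes were above 0 and 14 below 0. Among 14 genes described elsewhere as Zac1 targets, 4 could be tested and 1 passed, Socs3, a suppressor of cytokine signalling, which rose 1.55-fold; adjusted over the list alone, Pparg was also higher and Tcf4 was lower.

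A few matrix genes rose. Of 29 collagens and other structural matrix genes tested, 3 rose and 0 fell. They were Emilin1 (log2 fold change 2.01, SE 0.41, adjusted p = 0.0117), Col1a1 (1.54, SE 0.33, adjusted p = 0.0164) and Thbs1 (0.42, SE 0.09, adjusted p = 0.0205). Emilin1 and Col1a1 stayed low, at 1.55 ± 0.338 and 1.89 ± 0.344 CPM in Zac1. Over the list alone, 6 were higher and 1 was lower, and camera placed the list higher (adjusted p = 0.0296; adjusted p = 0.309 with an estimated correlation). That call ended without Zac1 4 (adjusted p = 0.0515) and with GC offsets (0.639 and turned to lower with the least-squares curve, 0.419 with the robust curve). Of 24 matrix crosslinking and remodelling genes, 2 rose, among them Loxl4, a lysyl oxidase-like enzyme (0.31, SE 0.08, adjusted p = 0.0428), also 2 over the list alone (camera adjusted p = 0.00191; adjusted p = 0.309 with an estimated correlation). Tgfb1 rose (0.52, SE 0.1, adjusted p = 0.00731), the only one of 30 TGF-beta pathway genes to pass, also over the list alone. That list did not pass camera (adjusted p = 0.07); it passed without Zac1 5 (0.0462) and on unscaled counts (0.0091). Single libraries decided these gene calls. Emilin1 was lost without EGFP 3 or Zac1 5 (adjusted p up to 0.072), and Col1a1 without EGFP 2 or Zac1 6 (up to 0.1). Thbs1 was lost without EGFP 1, EGFP 3, Zac1 5 or Zac1 6 (up to 0.134). Loxl4 was lost without any library but Zac1 4 (up to 0.228) with the least-squares GC curve (0.119), with a mean count of at least 50 (0.0655), with no trend in the variance (0.0549) and with limma on log2(CPM + 1) (0.0526), and Tgfb1 without EGFP 3 (0.066).

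Lipid metabolism genes showed few changes. Of 24 genes of fatty acid and triglyceride synthesis, Acacb, an acetyl-CoA carboxylase, rose from 0.446 ± 0.313 to 2.17 ± 0.941 CPM (log2 fold change 2.26, SE 0.45, adjusted p = 0.0102; lost without EGFP 3 or Zac1 5, up to 0.086), and it was also the only one over the list alone (camera adjusted p = 0.618). Of 29 fatty acid oxidation and ketogenesis genes 0 passed, over all genes or the list alone. Pdk4 was at 0.51 (adjusted p = 0.0589) and Ppargc1a at -0.74 (adjusted p = 0.0923). The list did not pass camera (adjusted p = 0.0645). It passed as lower without EGFP 1 or Zac1 6 (down to 0.0406), with no filter on low counts (0.0312) and with GC offsets (0.0438 with the least-squares and 0.0275 with the robust curve). Pdk4 passed without EGFP 3 or Zac1 4 (down to 0.0203) with GC offsets (0.0262 and 0.0381), with no filter on low counts (0.00398), with voom quality weights (0.0104), without EGFP 1 and Zac1 4 together (0.0131) and on unscaled counts (0.00221). Ppargc1a passed with no filter (0.0271). Of 37 hepatocyte markers among the counted genes, 18 were below the count minimum, and 2 had 0 reads in every library. How full a hepatocyte program these cells express was not tested. Of the 19 hepatocyte markers tested, 2 rose and 2 fell. Those higher included the transcription factor gene Prox1 (0.45, SE 0.07, adjusted p = 0.0019), and Ttr and Hp, both secreted plasma proteins, were lower. Over the list alone 3 were higher and 2 lower. The median of that list was 0.03, its mean -0.04 and the camera direction lower (adjusted p = 0.813).

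Inflammatory and immediate-early genes included more rises than falls. Of 27 NF-kappaB and inflammatory genes, 6 rose and 2 fell, Ptgs2 and Il6, named here after their values were known. Icam1, a leukocyte adhesion molecule, rose 2.14-fold, from 30.9 ± 2.89 to 66.1 ± 6.46 CPM (SE 0.09 on the log2 scale, adjusted p = 7.48e-06), the chemokine gene Cxcl2 1.81-fold, Socs3 1.55-fold and Nfkb2 1.32-fold (adjusted p at most 0.00339; Nfkb2 was lost with the least-squares GC curve, at 0.0545). Over the list alone 9 were higher and 2 lower (camera adjusted p = 0.000935; adjusted p = 0.479 with an estimated correlation). Of 29 immediate-early and serum-response genes, 6 rose and 0 fell, with 16 higher and 1 lower over the list alone (camera adjusted p = 9.76e-08; adjusted p = 0.297 with an estimated correlation). Fosb rose 2.72-fold, the growth factor gene Hbegf 1.32-fold, Klf10 1.27-fold and Egr1 1.53-fold; Egr1 was lost without EGFP 1, EGFP 3, Zac1 5 or Zac1 6 (adjusted p up to 0.169), with a mean count of at least 50 (0.0548) and with robust variance (0.0652). Of 46 interferon-stimulated genes 0 passed, over all genes or the list alone, while 40 of the 46 fold changes were below 0 (median -0.16; camera adjusted p = 1.35e-05; adjusted p = 0.527 with an estimated correlation). Ifit2 was at -0.39 (adjusted p = 0.0627) and passed without EGFP 1 or Zac1 4 (down to 0.000231), without both (1.64e-13), with no filter on low counts (4.24e-07), with voom quality weights (0.00354) and with DESeq2 (0.0101); of these, the fits without both libraries and with no filter shared the variance almost wholly over genes. The interferon call ended without Zac1 4 (adjusted p = 0.101).

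Stress-response genes included more falls than rises. Of 25 NRF2 and oxidative stress genes, 4 fell and 0 rose. They were Gstm1, a glutathione transferase (log2 fold change -0.3, adjusted p = 0.00547), Nqo1, a quinone reductase (-0.46, adjusted p = 0.0279), Gclc, a subunit of the enzyme that starts glutathione synthesis (-0.21, adjusted p = 0.0288), and the cystine transporter gene Slc7a11 (-0.21, adjusted p = 0.0422). Over the list alone 9 were lower and 1 higher (camera adjusted p = 1.09e-05; adjusted p = 0.297 with an estimated correlation). Of 17 heat shock genes, Hspa1a and Hspa1b fell, 3 over the list alone (camera adjusted p = 0.00175, and 0.297 with an estimated correlation). In the heat shock list 13 fold changes were below 0. Its median was -0.07 and its mean -0.26, which the 2 near-identical Hspa1 copies pull down. Of 35 genes of the unfolded protein and integrated stress responses, 4 fell and 1 rose (1 higher and 6 lower over the list alone). Slc7a11, which is on the NRF2 list too, is counted among these 4 falls as well. The chaperone genes Dnajb9 (-0.43, adjusted p = 0.00404) and Hspa5 (-0.17, adjusted p = 0.0381) and the stress sensor Atf6 (-0.27, adjusted p = 0.00595) were lower, while Atf3, an inducible transcription factor, was higher (0.44, adjusted p = 0.00731). The list of the unfolded protein and integrated stress responses passed camera as lower (adjusted p = 0.0183, and 0.527 with an estimated correlation). It did not pass without EGFP 2, EGFP 3 or Zac1 4 (up to 0.426). It passed as lower with the least-squares (0.000123) and the robust GC curve (0.000511). Nqo1 was lost without EGFP 1, EGFP 2, Zac1 5 or Zac1 6 (up to 0.171), and Gclc and Slc7a11 without EGFP 1, EGFP 3, Zac1 5 or Zac1 6 (up to 0.193 and 0.217). Hspa5 was lost without EGFP 2, EGFP 3, Zac1 5 or Zac1 6 (up to 0.182), Atf6 without Zac1 5 (0.0831) and Atf3 without EGFP 3 or Zac1 6 (up to 0.0629). With the robust GC curve Hspa5 (0.0733) and Slc7a11 (0.0785) did not pass, while both passed with the least-squares curve (0.0207 and 0.0441). Neither passed with a mean count of at least 50, with no trend in the variance or with scaling to the total without Plagl1 (0.0537 to 0.0932); Hspa5 was also lost with upper-quartile scaling (0.0791), scaling to the total (0.0512) and limma on log2(CPM + 1) (0.0855), and Gclc with no trend (0.0602). On unscaled counts Gstm1, Nqo1, Gclc, Slc7a11, Dnajb9 and Atf6 did not pass (0.0547 to 0.943), Hspa5 turned to higher (0.768) and the list of the unfolded protein and integrated stress responses did not pass (0.759).

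Cell-cycle lists passed camera as higher with small medians. Of 35 G1/S and DNA replication genes, only Ccne1, a cyclin of S-phase entry, rose (0.41, SE 0.1, adjusted p = 0.0292), also over the list alone, with 30 of 35 fold changes above 0 (median 0.07; camera adjusted p = 0.00175; adjusted p = 0.412 with an estimated correlation). Of 36 G2/M genes 0 passed, over all genes or the list alone (median 0.04; camera adjusted p = 0.0383; adjusted p = 0.498 with an estimated correlation). Plk1 was at 0.17 (adjusted p = 0.0904; 0.0498 without Zac1 4) and Tacc3 at 0.14 (adjusted p = 0.192). Plk1 also passed with voom quality weights (0.0142) and without EGFP 1 and Zac1 4 together (0.0288), and both genes on unscaled counts (0.00193 and 0.00334). Ccne1 was lost without EGFP 2, EGFP 3, Zac1 5 or Zac1 6 (up to 0.196). It was also lost with GC offsets, at a log2 fold change of 0.33 (0.0698) with the least-squares and 0.38 (0.0537) with the robust curve. The G1/S list did not pass without Zac1 4 (0.0643). The G2/M list did not without EGFP 2, EGFP 3 or Zac1 4 (up to 0.25), with no filter on low counts (0.0652) or with median-of-ratios scaling (0.0521). With the least-squares and robust GC curves, camera adjusted p was 0.00518 and 0.000292 for G1/S and 0.000493 and 3.78e-05 for G2/M, both higher. Of 9 mitochondrially encoded genes 0 passed, over all genes or the list alone. The gene mt-Nd5 was at -0.14 (adjusted p = 0.183) and mt-Cytb at -0.09 (adjusted p = 0.361). The first passed with no filter on low counts (0.0283), with voom quality weights (0.0253) and without EGFP 1 and Zac1 4 together (0.00312). That list passed as lower (camera adjusted p = 0.0417; adjusted p = 0.527 with an estimated correlation), but not without EGFP 1, EGFP 3, Zac1 5 or Zac1 6 (up to 0.393) or on unscaled counts (0.738), and turned to higher with both GC curves (0.254 and 0.419).

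Camera called 11 of the 23 lists with the preset correlation and 0 of the 23 with an estimated one. The rotation test fry, which asks whether the genes of a list move one way and compares them with no other genes, called 8. Among the 11 these were both matrix lists (adjusted p = 0.0225 and 0.0279), NRF2 (0.0225), heat shock (0.0225) and immediate-early genes (0.0256). Fry did not call the interferon (0.537), NF-kappaB (0.142), G1/S (0.153), G2/M (0.208), unfolded protein (0.459) and mitochondrial (0.483) lists, and it called TGF-beta (0.0225), hypoxia (0.0387) and the insulin and IGF axis (0.0256), which camera did not. The lists that did not pass camera included hypoxia response, with 3 of 21 genes higher (Mxi1, Car9 and Egln3) and 4 over the list alone (camera adjusted p = 0.217), and glycolysis, with 1 of 18 higher (Eno2), also over the list alone (adjusted p = 0.0645). Of 35 p53 targets 2 fell, Plk2 and Mdm2, with 2 higher and 3 lower over the list alone (adjusted p = 0.143). The members of these 3 lists were chosen after their values were seen. In the insulin and IGF axis 0 of 14 passed (adjusted p = 0.0654), in cholesterol synthesis and uptake 0 of 24 (adjusted p = 0.813) and in ribosomal proteins 0 of 41 (adjusted p = 0.813), also over each list alone. Glycolysis passed without EGFP 1 or Zac1 4 (down to 0.014), without both (0.00478), with a mean count of at least 50 (0.0146), with upper-quartile scaling (0.0436), with scaling to the total without Plagl1 (0.045) and on unscaled counts (0.0184). The insulin and IGF list passed with a mean count of at least 50 (0.0334), without EGFP 1 and Zac1 4 together (0.0478) and on unscaled counts (0.0337). The p53, insulin and cholesterol lists passed without EGFP 1 (0.0453 each, with the cholesterol list turned from lower to higher). The p53 and ribosomal lists passed as lower with the least-squares GC curve (0.017 and 0.0153), and the ribosomal list as higher on unscaled counts (0.03). For the cholesterol list the mean was 0.01 and for ribosomal proteins the median was -0.01 and the mean 0.01, with a camera direction of lower for both, which for ribosomal proteins turned to higher with upper-quartile scaling and with scaling to the total without Plagl1. Where edgeR called 0 genes of a list, the number at an unadjusted p under 0.05 was 6 for fatty acid oxidation, 13 for interferon-stimulated, 2 for G2/M, 1 for mitochondrial, 4 for insulin and IGF, 1 for cholesterol and 1 for ribosomal genes. DESeq2 called 2 interferon-stimulated genes, both lower, and 0 in the other 6 of these lists; voom with quality weights called 3, 7, 1, 2, 2, 1 and 2 genes in the same order. Markers of fibroblasts and stellate cells, leukocytes and endothelium were mostly below the count minimum, while those of cholangiocytes and progenitors mostly were not. Some markers of other cell types were well expressed in both groups. Named after their values were known, Krt19 was at 258 ± 18.1 CPM in EGFP and 253 ± 8.39 in Zac1, and Vim at 1140 ± 21.1 and 1200 ± 42.8. Of 12 cholangiocyte and progenitor markers 7 were tested and 0 passed, with 1 lower over the list alone (camera adjusted p = 0.6), 2 at an unadjusted p under 0.05, 0 by DESeq2 and 2 by voom. Only 1 of 21 fibroblast and stellate cell markers (Vim), 2 of 21 leukocyte markers and 1 of 13 endothelial markers reached the count minimum. Of these, 0 were past the test, 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or voom.

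**Figure D3:**
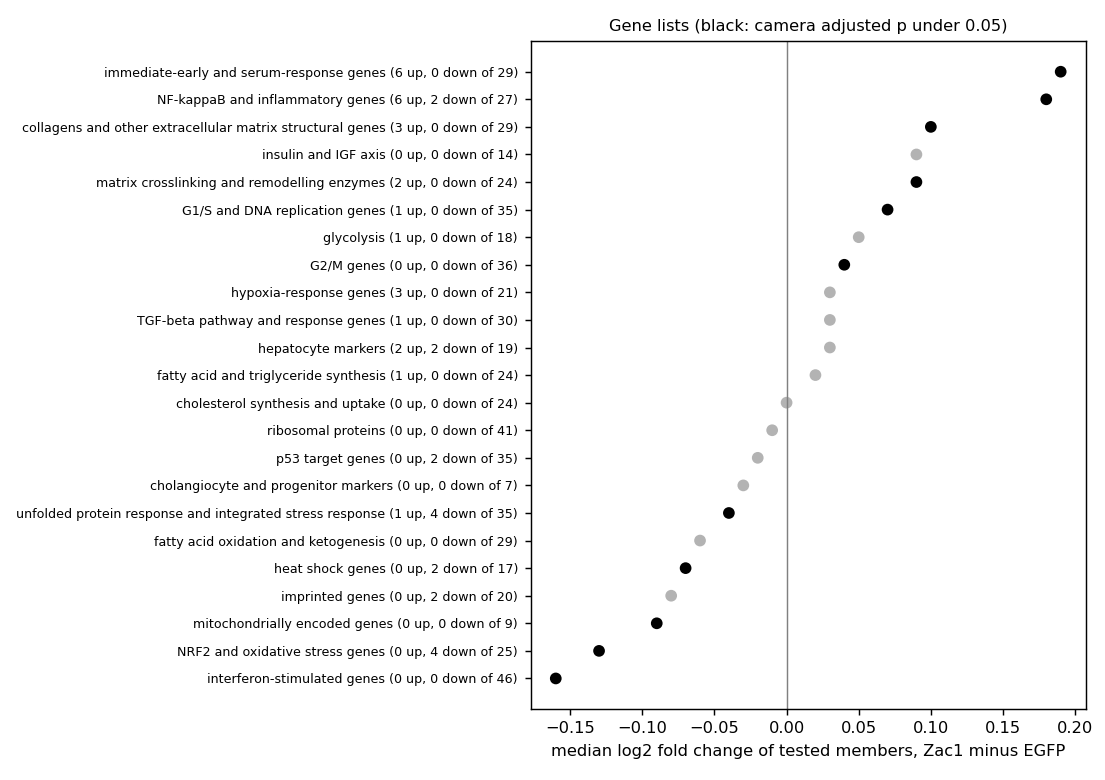
Median log2 fold change (Zac1 minus EGFP) of the tested members of each of the 23 gene lists, with the numbers of members higher and lower in brackets; black points mark the 11 lists past camera with the preset correlation, of which 0 pass with an estimated one. Medians run from -0.16 for interferon-stimulated genes to 0.19 for immediate-early genes.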

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

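The alternatives with median-of-ratios scaling, limma on log2(CPM + 1), GC offsets, and EGFP 1 and Zac1 4 left out together were chosen after seeing the data. Limma on unscaled counts is the test written before the data were examined, kept as an alternative once the values proved to be counts. Of the 2 GC versions, the robust curve was chosen after the least-squares result was seen. The log2 fold change of Plagl1 stayed between 10.58 and 11.05 with 1 library left out and was past the threshold in every alternative run. No filter on low counts gave 979 changed genes (731 higher, 248 lower, 406 at least 2-fold), and a mean count of at least 50 gave 241 (190, 51 and 37). With no filter the variance was also shared almost wholly over genes, with infinite prior degrees of freedom against 10 in the main comparison and 8.89 with the stricter filter. The cause of either count was not tested. Limma-voom with library quality weights gave 1297 (797 and 500) and kept all 459 calls; limma-trend on log2(CPM + 1) gave 89 changes of at least 2-fold. Limma on unscaled counts gave 3207 (3184 and 23, 310 at least 2-fold) with a median shift of 0.199 from depth alone; there Hspa5 (log2 fold change 0.03, adjusted p = 0.768, not past the test) and the ribosomal list (adjusted p = 0.03) turned to higher, as did, not past the test, mt-Nd5 and mt-Cytb (log2 fold changes 0.06 and 0.11) and the cholesterol and cholangiocyte lists (adjusted p = 0.957 and 0.813). The least-squares GC curve gave 953 (332 higher and 621 lower) and kept 369 of the 459 calls, with a median log2 fold change of -0.043. The robust curve gave 476 (365 and 111) and kept 403, with a median of -0.002. The matrix list turned to lower with the least-squares curve (adjusted p = 0.639) and the mitochondrial list to higher with both (0.254 and 0.419); fatty acid synthesis (0.825) and glycolysis (0.667) turned to lower with the least-squares curve. None of the following turned lists passed. The ribosomal list turned to higher with upper-quartile scaling (0.944), scaling to the total without Plagl1 (0.925), a mean count of at least 50 (1) and EGFP 1 and Zac1 4 left out (0.217); the hepatocyte list with a mean count of at least 50 (1) and fry (0.757); and the cholesterol list with fry (0.966) and EGFP 1 and Zac1 4 left out (0.543). Without EGFP 1 and Zac1 4 together, 1461 genes changed (853 and 608), 454 of the 459 among them, with 1560 prior degrees of freedom; the cause was not tested. With 1 library left out these were 8 to 16.4, the highest without Zac1 4. Leaving out 1 library gave 206 to 963 changed genes, 187 to 584 higher, 19 to 379 lower, 122 to 205 changed at least 2-fold and 7 to 15 lists; the extremes came without Zac1 5 (206, 187 and 19), without Zac1 4 (963, 584, 379 and 7 lists) and without EGFP 1 (15 lists), and the cholesterol list turned to higher without EGFP 1 (adjusted p from 0.0453 to 0.817 with 1 library left out). Lists uncalled throughout with 1 library left out that changed direction for some were fatty acid synthesis (0.0607 to 0.956), hepatocyte (0.473 to 0.956) and ribosomal (0.0649 to 0.968). Of 48 named genes past the test, 26 stayed past it with each library left out. No list passed camera with an estimated correlation (0 of 23) and 8 passed fry, against 11 in the main comparison. Over all alternatives, 1147 of 1284 values of named genes and 377 of 460 of lists kept direction and side of the threshold; 105 and 35 were weaker, 29 and 24 stronger, 3 and 24 reversed. Prior counts of 0.5 and 5 alter fold changes but not the edgeR p-values of genes. The gene values of those alternatives therefore kept their side of the threshold by construction, which raises the first share. No paired analysis was run. The labels do not say whether libraries of the groups were handled in pairs, and their numbers do not settle it. Whether EGFP 1 and Zac1 4, both apart on the second component, form such a pair was not tested. Genes of a few reads per library have wide intervals at this depth.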

Other observations

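The lists and genes of this and the next paragraph were chosen, and the tests with the robust GC curve, the receptor-gene reads and the summed Hspa1 count were run, only after the results had been seen. Of 8 tested Wnt ligands 3 were higher, and of 14 tested feedback regulators and common beta-catenin targets 3 were. Members had been seen before these lists were written, so no enrichment is tested. Wnt6 had 2 reads in all EGFP libraries and 189 in all Zac1 libraries, a ratio of 82.1 (95% interval 22.4 to 683), Wnt10b had 1 and 73 (63.4, 11 to 2540), and Wnt7b rose 1.49-fold. Axin2, a feedback inhibitor of the pathway, rose 6.96-fold, from 0.648 ± 0.189 to 4.56 ± 0.253 CPM (SD, n = 3). Notum, which inactivates Wnt proteins, had 0 reads in EGFP and 62 in Zac1, at least 18-fold higher against 3 counts over the group.

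Of 21 tested synaptic and neuronal genes, 10 were higher, but several of those members were what prompted the list. Among 5 abundant neuronal transcripts, listed separately, Snap25 was at 0.761 ± 0.172 CPM in EGFP and 0.848 ± 0.161 in Zac1, and Syt1 at 4.95 ± 0.724 and 3.88 ± 0.599. Of 15 tested Notch genes 2 were higher, Dll1 and Hey1. Ddn and Cecr2 had 0 reads in EGFP and were at least 19.7-fold and at least 25.2-fold higher.

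More genes rose than fell at least 2-fold, 175 against 11. For depth, library totals ran from 14801240 to 18302538, and the fit already scaled for them. A depth difference of that size is too small to be the whole cause of changes of at least 2-fold. Thinning could not have undone most of them, so its result was largely set in advance. With every library thinned to the lowest total, 155 rose and 11 fell. For GC content, median log2 fold changes ran from -0.09 in the lowest to 0.103 in the highest GC decile of tested genes. A trend of that size is too small to be the whole cause of changes of at least 2-fold. Offsets that remove only this trend could not have undone most of them, so their result was largely set in advance. They left 163 higher and 15 lower for the least-squares curve and 168 and 11 for the robust one. GC effects of another form were not tested. DNA carried over into the Zac1 libraries would raise reads in genes that hepatocytes do not use, but the share of reads in 1929 olfactory, vomeronasal and trace-amine receptor genes had a Zac1 to EGFP ratio of 0.865, with an upper bound of 0.986. In genes chosen as low in 2 EGFP libraries, the third EGFP library held 2614 to 2982 reads and the Zac1 libraries 4710 to 5936, while the mirror choice gave 2734 to 3133 in the third Zac1 library and 2431 to 2725 in EGFP. Whether the genes respond to Zac1 itself was not tested and stays open.

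Changes of under 2-fold and the shifts of gene lists are less secure. Of the 273 smaller calls, 186 were still called in the same direction with the least-squares GC curve and 221 with the robust one. Of the 11 lists, 9 and 9 were. GC bias may thus account for part of them. The offsets remove only a smooth trend on the GC content of the longest transcript, so bias of another form may remain in the rest. The number of lower genes was 81 without offsets, 621 with the first curve and 111 with the second. The median log2 fold change of all tested genes was -0.002, -0.043 and -0.002 in turn. Whether the shape of the curve or this shift made the difference was not tested. Whether Zac1 itself or library preparation made the GC trend was not tested and stays open: correlations of each library's deviations with GC were -0.38, 0.07 and -0.31 in EGFP and -0.21, 0.35 and 0.54 in Zac1.

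Among the 10 splits of the 6 libraries into 3 and 3, the real one was the 1 with the most changed genes (459, highest other 17), higher genes (378, highest other 15), lower genes (81, highest other 15, the larger side being taken for both directions since the sides of a mixed split are arbitrary), at least 2-fold changes (186, highest other 0) and lists (11, highest other 10); 10 splits are too few for a share under 0.05. The split with 17 genes and 10 lists set EGFP 1, EGFP 3 and Zac1 4 against the rest, the 3 libraries with negative GC correlations, which points to a structure of the samples. At an unadjusted p under 0.05 it gave 2360 genes, more than the 1921 of the real split. With GC offsets that split gave 5 lists for the least-squares and 6 for the robust curve, against 12 and 10 for the real split and 8 for the highest other under either.

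Lower Hspa1a and Hspa1b might come from reads dividing differently between the near-identical copies. Both copies were lower, so their summed count had to be lower as well and is no separate test. Its log2 fold change was -1.81 (SE 0.14, unadjusted p = 4.48e-09 by the edgeR model fitted across all genes). Reads moving from 1 copy to the other would leave 1 of them higher, and neither was. Handling or transfection stress that differed between the groups stays open, since the labels give nothing to test it with.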
